A study of Mus musculus with 4 samples.

How the data were processed

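The 4 deposited matrices, 1 per library, hold UMI counts as whole numbers, where each unique molecular identifier (UMI) marks a captured transcript. Per the file headers they were written by Cell Ranger 4.0.0, while the submitters' processing notes give Cell Ranger 3.0.1 and the mm10 genome. No further filter or scaling by the authors was visible in the values, and the lowest total of any barcode at 0 h in the IL-22-negative library was 500.0 UMIs. Per the labels' protocols, liver leukocytes of IL-22-BFP reporter mice were freed with collagenase and DNase, enriched on Percoll, sorted as CD45-positive cells into reporter-negative and reporter-positive fractions, and made into 10x Single Cell 3' v2 libraries. The labels do not give the number of mice behind a library.

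Of the 32285 features, 32158 (99.6%) match a gene of GENCODE vM21, and 38 symbols stand for more than 1 gene ID. No feature is named for BFP, so the reporter transcript itself could not be counted. Of the 379 genes in the fixed lists, 1 is missing from the features (Mx1). In GRCm38 coordinates, Il22 lies on the plus strand of chromosome 10 from 118204942 to 118210047 and Il17a on the plus strand of chromosome 1 from 20730905 to 20734496. S100a8 lies on the plus strand of chromosome 3 from 90668978 to 90670035, and Cxcl10 on the minus strand of chromosome 5 from 92346638 to 92348889.

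Barcodes with at least 200 genes and under 10% mitochondrial UMIs were kept, and Scrublet calls were removed library by library. The filter removed 254 and 132 barcodes of the IL-22-negative libraries of 0 h and 12 h, and 11 and 28 of the IL-22-positive ones. Scrublet's automatic threshold called 1 of 10231 barcodes of the IL-22-negative library of 12 h, which is far below the expected 0.8% per 1000 cells. The threshold of the 0 h library was therefore used there, a choice made after its result was seen. Doublet removal then took 262, 393, 0 and 3 barcodes in the same order of libraries. The kept cells number 8039 and 9706 in the IL-22-negative libraries and 289 and 1347 in the IL-22-positive ones, with median depths of 1799, 2175.5, 3387 and 3712 UMIs.

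Clusters were made from all 4 libraries together, from the log of counts per 10000, 2000 variable genes without antigen receptor segments and without Il22, 30 principal components, 15 neighbours and Leiden resolution 1. This gave 22 clusters, and the lymphocytes were clustered again into 12 sub-clusters. Clusters were named from 26 cell-type marker lists, and the suffix "-like" marks such a name. No cluster was led by the hepatocyte, endothelial, stellate, epithelial, erythroid, platelet, eosinophil, ILC2, ILC3 or MAIT lists. CD4, CD8, regulatory, gamma-delta and iNKT markers served to describe sub-clusters of T-cell-like cells and not as classes. Clusters 13 and 16, led by interferon-response and cell-cycle genes, held several cell types, so their 508 cells with at least 2 markers were placed cell by cell. That step, the minimum of 10% of a cluster's cells for its leading genes, and leaving a cluster that shares T and B markers unnamed were decided after the clusters were seen.

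UMIs were summed per library and class and given as CPM, which is 100.0 times the counts per 10000 UMIs of that sum. Intervals on shares, sums and ratios are exact 95% intervals (Poisson, binomial or Clopper-Pearson) that cover counting error alone. Those on correlations are the middle 95% of 1000 resamples of genes, which treat genes as independent. With 1 library per group there are no replicates, so no gene is called by a test. A ratio therefore compares 2 libraries, not 2 conditions. A sum of 0 was set to 3 UMIs, and its ratio is given as "at least" or "at most" on that basis. Such a value is not a 95% limit, and the exact interval can reach further towards no difference. The rule for named genes was fixed before the data were examined. Eligible genes have at least 100.0 CPM and 50 UMIs in the higher sum, and mitochondrial and ribosomal protein genes, antigen receptor segments, Xist, Y-linked genes and the hepatocyte free-RNA lists are left out. The 10 highest and 10 lowest ratios were named for each of the 4 T-cell-like comparisons, and the 5 highest and 5 lowest for each other IL-22-negative class with at least 50 cells at both times. Comparisons of monocyte-like cells of the IL-22-positive libraries were added after the data were seen and used the rule with 10 and 10. Genes named outside the rule come from the fixed lists, from the genes always reported, or are said to be chosen after their values were seen. Some results that the rule or the clusters gave are not reported here.

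The 17 program lists were also fixed before the data were examined: type 17, type 1 and cytotoxic, T cell receptor and activation, interferon response, interferon gamma response, immediate early and dissociation, inflammatory cytokines and chemokines, NF-kappaB targets, tissue residency, recirculation, proliferation, glycolysis and hypoxia, MHC class II, neutrophil activation, complement and scavenger genes of Kupffer cells, and 2 lists of hepatocyte transcripts as a gauge of free RNA. A member was measured with at least 10 UMIs in the 2 sums together. It counted as higher or lower when its ratio passed 1.5 either way and its interval left out 1. The median log2 ratio of a list is given with its percentile among 10000 random lists matched on abundance in 20 bins. The match was on mean CPM until the simulated data showed a bias, and is now on summed UMIs. Both versions were run on these data.

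The comparisons were tested on simulated data with the sums of each real comparison, with 200 genes changed, 50 at each of 4 sizes. Between IL-22-positive and IL-22-negative T-cell-like cells of 0 h, with 1437 genes measurable, 84% of true doublings and 100.0% of 4-fold rises were called, and 3.23% of unchanged genes were called. For the IL-22-positive T-cell-like cells over time, 56% of doublings were called and 3.39% of unchanged genes. For the IL-22-negative T-cell-like cells over time, 94% of doublings were called and 1.32% of unchanged genes. The intervals held the true ratio for 95.8% to 96.2% of genes in these comparisons. These rates come from simulated sums and do not cover genes whose UMIs lie in a few cells. For such genes single cells can set a ratio, and the rate of false calls was not measured. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.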

Results

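Leukocytes of the mouse liver were profiled by single-cell RNA sequencing before (0 h) and 12 h after MC38 colon carcinoma cells were injected into the spleen, from where they reach the liver through the portal vein. The cells came from reporter mice in which BFP marks Il22 expression. Sorting split the CD45-positive cells of each time into an IL-22-negative and an IL-22-positive library. The question behind the series is which liver leukocytes make IL-22, a cytokine that acts on epithelial and other non-haematopoietic cells, when cancer cells arrive. Each of the 4 groups has 1 library, and no library follows an injection without cancer cells, so the time after surgery and the arrival of the cells were not separated.

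Il22 transcripts were rare in every library and highest in the IL-22-positive cells of 0 h. There, 3 of 289 cells (1.04%, 95% interval 0.215 to 3.00) held 6 Il22 UMIs, at 5.29 CPM (1.94 to 11.5). In the IL-22-negative library of 0 h, 7 of 8039 cells (0.0871%, 0.0350 to 0.179) held 16 UMIs, at 0.9 CPM (0.514 to 1.46). At 12 h, 1 of 9706 IL-22-negative cells (0.0103%) held 1 UMI, and none of the 1347 IL-22-positive cells held any. A count of 0 allows up to 0.223% of cells with a captured UMI and 0.598 CPM in that last library. As background, 1 of 4002 B-cell-like cells of all libraries (0.0250%) held an Il22 UMI, at median depths of 1718.5 and 1598 UMIs in the IL-22-negative B-cell-like cells of 0 h and 12 h against 2438 and 2318 in the T-cell-like cells. With every cell thinned to 1000 UMIs, the share was 1.08% in the IL-22-positive and 0.0807% in the IL-22-negative library of 0 h. The share of IL-22-negative cells of 0 h lies within the interval of that background, which reaches 0.139%. That of 12 h lies below the background share itself, so Il22 expression was not detectable at this depth in either library of 12 h.

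The IL-22-positive fractions consisted mainly of monocyte-like cells, whose share was set by the sort on blue fluorescence. Monocyte-like cells made up 50.5% (44.6 to 56.4) of the IL-22-positive library of 0 h and 78.8% (76.6 to 81.0) of that of 12 h, against 1.77% and 6.07% of the IL-22-negative libraries. Macrophage-like cells were named from a joint marker list of Kupffer cells, the resident macrophages of the liver, and other macrophages. Whether they include Kupffer cells was not tested. They made up 12.1% (8.58 to 16.4) and 4.68% (3.61 to 5.94) of the IL-22-positive libraries and 0.0746% and 0.0824% of the IL-22-negative ones. T-cell-like cells formed 13.8% (10.1 to 18.4) of the IL-22-positive library of 0 h and 2.82% (2.0 to 3.85) of that of 12 h, which is 40 and 38 cells. B-cell-like cells formed 10.7% and 1.71% of the same libraries. None of the 1208 IL-22-positive monocyte-like cells held an Il22 UMI. That 0 allows up to 0.282% of those of 12 h to hold a captured Il22 UMI, at a median depth of 4106 UMIs, and sets no limit on how many express the gene.

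A cluster led by Arg1, an arginase of alternatively activated and tumour-associated macrophages, and Pf4, a chemokine, was found at 12 h alone at the main resolution. It held 38 cells (2.82%) of the IL-22-positive and 32 cells (0.330%) of the IL-22-negative library of 12 h, and 0 cells in both libraries of 0 h. At the finer resolution a cluster led by the same genes took 5.63% and 7.53% of the IL-22-negative and IL-22-positive monocyte-like cells of 0 h, and 11.7% and 19.5% of those of 12 h. Neutrophil-like cells went from 0.261% to 0.824% of the IL-22-negative cells and made up 0.346% and 1.63% of the IL-22-positive ones. Monocyte-like, macrophage-like and neutrophil-like cells and the Arg1 and Pf4 cluster together formed 63.0% (57.1 to 68.6) of the IL-22-positive library of 0 h and 88.0% (86.1 to 89.7) of that of 12 h.

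**Figure D1:**
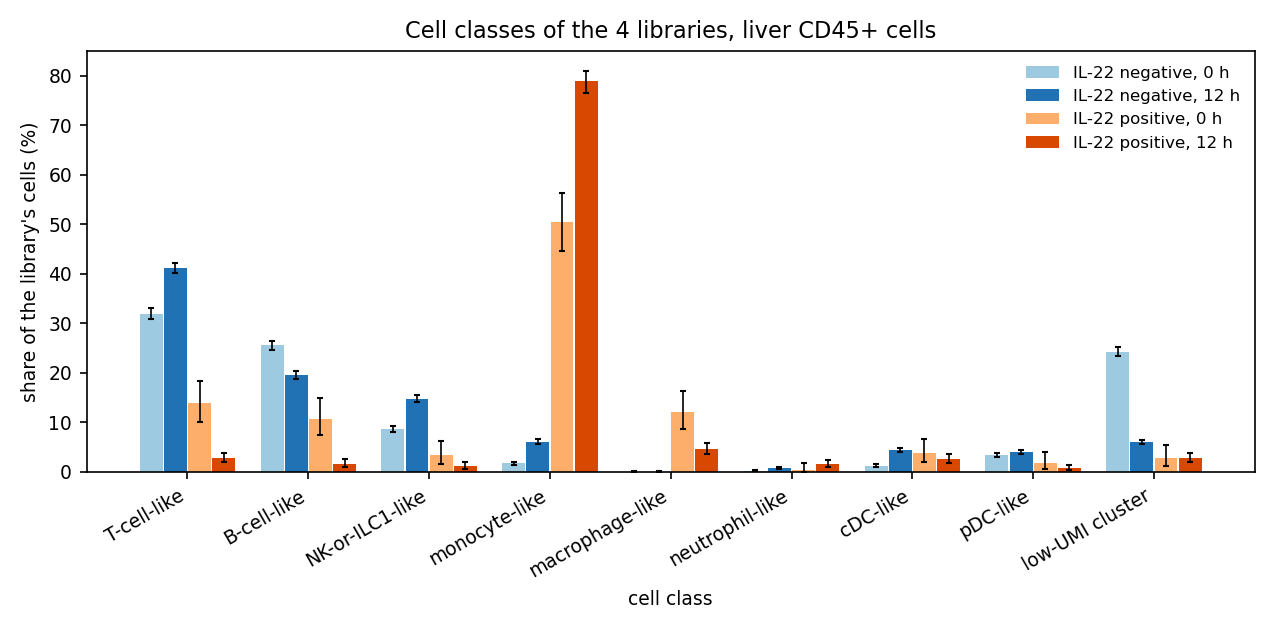
Share of each library's cells (%) in 9 groups of cells, with light and dark blue bars for the IL-22-negative libraries of 0 h and 12 h, light and dark orange bars for the IL-22-positive ones, and exact 95% intervals as error bars. Monocyte-like cells fill 50.5% and 78.8% of the IL-22-positive libraries and 1.77% and 6.07% of the IL-22-negative ones.

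Among IL-22-negative leukocytes, monocyte-like and NK-or-ILC1-like cells took a larger share at 12 h than at 0 h, and B-cell-like cells a smaller one. Monocyte-like cells went from 1.77% (1.49 to 2.08) to 6.07% (5.6 to 6.56), a 3.44-fold ratio of shares. NK-or-ILC1-like cells, the innate cytotoxic lymphocytes of the liver, went from 8.63% (8.03 to 9.27) to 14.8% (14.1 to 15.5). Conventional dendritic cells (cDC-like), which present antigen to T cells, went from 1.31% (1.07 to 1.58) to 4.45% (4.05 to 4.88). T-cell-like cells went from 32.0% (31.0 to 33.0) to 41.2% (40.3 to 42.2) and B-cell-like cells from 25.6% (24.6 to 26.5) to 19.5% (18.7 to 20.3). Plasmacytoid dendritic (pDC-like) cells formed 3.48% and 3.98%, plasma-cell-like cells 1.22% and 1.46%, and basophil-like cells 0.485% and 0.258%. Clusters of cells with few UMIs went from 24.3% to 6.04% of the library. With those left out, the ratio of T-cell-like shares was 1.04 in place of 1.29, while that of monocyte-like shares was 2.77 and that of NK-or-ILC1-like shares 1.38.

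Trav11 and Traj18, which form the invariant receptor chain of iNKT cells, were counted mainly in a sub-cluster of T-cell-like cells led by Cd40lg, Cxcr6 and Zbtb16, which encodes the PLZF transcription factor of innate-like T cells. It held 27.3% at 0 h and 36.6% at 12 h of the sub-clustered IL-22-negative T-cell-like cells. Its 682 cells of 0 h held 18 Trav11 and 18 Traj18 UMIs, and its 1337 cells of 12 h held 34 and 44, at 10.4 and 10.8 CPM for Trav11. Ifng, the type 1 cytokine, stood at 319 CPM (293 to 346) and 291 CPM (272 to 310) in it, and it held 0 Il22 UMIs, with limits of 1.73 and 0.954 CPM. In the IL-22-positive libraries, 4 cells of 0 h and 14 of 12 h belonged to it. In 3' libraries most reads fall far from the variable segments, which limits these counts.

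At 0 h, IL-22-positive T-cell-like cells were higher than IL-22-negative ones in genes of type 17 lymphocytes. Il22 itself was 24.9-fold higher (7.77 to 70.3) and Il23r, the receptor for the type 17 cytokine IL-23, 22.5-fold (6.22 to 68.7). Of the 11 measured members of the type 17 list, 6 were higher and 0 lower, with a median log2 ratio of 1.12 at percentile 98.24 of the random lists. Il1r1, a receptor of IL-1, was 16.2-fold higher (2.87 to 63.0) on 3 UMIs, and the transcription factor genes Maf and Rora 2.05-fold (1.24 to 3.21) and 2.03-fold (1.12 to 3.38). The named genes with the highest ratios were Tmem176a, at 7.48-fold (5.58 to 9.86), and Tmem176b, at 5.90-fold (4.56 to 7.54), which lie side by side in the genome. Of the other named genes, Fcer1g was 3.10-fold, the actin-capping gene Capg 2.70-fold and S100a4 2.59-fold higher.

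Genes of antigen presentation were lower in the IL-22-positive cells of 0 h. Cd74, the MHC class II invariant chain, had a ratio of 0.274 (0.162 to 0.433). Of the 9 measured MHC class II genes 4 were lower and 0 higher, at a median log2 ratio of -1.42 and percentile 0. The list summed to 796 CPM in IL-22-negative and 255 CPM in IL-22-positive T-cell-like cells, against 49614 CPM in IL-22-negative B-cell-like cells. B-cell-like cells numbered 2056 of 8039 IL-22-negative and 31 of 289 IL-22-positive cells. Class II RNA from B cells and a difference between T cells were therefore not told apart. Cd28, the co-stimulatory receptor gene, had a ratio of 0.192 (0.0394 to 0.562). Cebpb, a transcription factor gene, had 969 UMIs against 0 and was at least 5.98-fold lower. It was also lower in monocyte-like cells of the same libraries, at 0.132, so it does not set T cells apart. The other named genes with low ratios were Kpna4, Pcbp1, Atp2b1, Samhd1, Nsd1, H2-T22 and Zfp36l2, between 0.222 and 0.397. The chemokine genes Ccl3 (at most 0.292, with 0 UMIs) and Ccl4 (0.485, 0.310 to 0.724) were lower, and they were the only 2 of 7 measured cytokine genes to differ.

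The other lists split few of their members between these cells. Of 12 type 1 and cytotoxic genes, Gzmk (2.95-fold, 1.66 to 4.87) and Gzma were higher, and of 18 T cell receptor and activation genes Egr2 was higher (4.32-fold, 1.13 to 11.8). Rgs1, a mark of resident T cells, was 2.04-fold higher (1.63 to 2.52), 1 of 12 residency genes, while Rgs2 was lower, and of 10 recirculation genes S1pr4 was 2.74-fold higher and S1pr5 11.6-fold, on 3 UMIs of 1 cell. The recirculation list as a whole leaned lower, with a median log2 ratio of -0.24 at percentile 7.21. Of the immediate early genes, Jun (1.99-fold) and Egr1 (1.53-fold) were higher and Hspa8 (0.571) lower, and of 14 glycolysis genes Hk2 was higher. Tnfaip3 (0.620) was the only lower gene of 12 NF-kappaB targets, and Cxcl10 (0.260, 0.0314 to 0.947) the only one of 11 interferon gamma genes. Single cells set several ratios. The histone genes Hist1h2ae (4.67-fold) and Hist1h2ap (3.22-fold) had ratios of 0.156 and 0.300 without the cell with most of their UMIs, H2afx went from 3.90 to 1.01, Gzma from 2.49 to 0.758 and AY036118 from 2.94 to 1.75. The same holds for the interferon list, where 3 of 16 genes were higher and Isg15 went from 2.12 to 0.0884, and for the proliferation list, where 4 of 13 were higher and all 21 Ube2c UMIs of the IL-22-positive cells lay in 1 cell.

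At 12 h, the 38 IL-22-positive T-cell-like cells were lower than the IL-22-negative ones in glycolysis and proliferation genes. Aldoa, a glycolytic enzyme, had a ratio of 0.147 (0.0634 to 0.290), Eno1 0.211 (0.0847 to 0.435) and Ldha 0.275 (0.132 to 0.507), and 5 of 14 glycolysis genes were lower with 0 higher (median log2 ratio -0.84, percentile 0.370). Of 13 proliferation genes, 5 were lower and 0 higher (percentile 0.340), among them Ube2c at 0.108 (0.00273 to 0.603) and Tubb5 at 0.443 (0.221 to 0.794). Of 12 type 1 genes 3 were lower, with the list at percentile 23.92. Gzmb, a granzyme, had a ratio of 0.260 (0.104 to 0.536), Cxcr3 0.312 and Ifng 0.376 (0.138 to 0.819). The type 17 list showed 0 of 13 genes higher or lower, with a median of 0.01. Among the named genes with the lowest ratios were Cd74 (0.0365, 0.000925 to 0.204), the tubulin genes Tubb4b (0.0409) and Tuba1c (0.1), Cd48, Sdf4, Tagln2 (0.145, 0.0722 to 0.259), Slc25a3 and Lgals9.

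All 10 named genes with low ratios were also lower in the IL-22-positive monocyte-like cells of 12 h, with a median log2 ratio of -1.46, and 5 of them in the B-cell-like cells. The difference was thus not particular to T cells. The named genes with high ratios included 4 that encode small mitochondrial proteins, Ndufa13 (1.56-fold), Uqcrq (1.53-fold), Atp5e (1.52-fold) and Cox7c (1.51-fold), with Sem1 (1.73-fold), 2410006H16Rik (1.48-fold) and Gm10076 (1.46-fold). Dbi went from 3.82-fold to 1.30-fold, Gstp1 from 2.22-fold to 1.07-fold and Gpx1 from 1.57-fold to 1.02-fold without the cell with most of their UMIs. Ribosomal protein genes took 43.1% of the UMIs of these cells and 34.0% to 35.1% in the T-cell-like cells of the other libraries. Scaling by the median ratio over genes shifted all log2 ratios of this comparison by 0.23.

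Single genes of other lists were lower as well in the IL-22-positive T-cell-like cells of 12 h. Rgs1 had a ratio of 0.246 (0.112 to 0.467), Cd69, an early activation and residency marker, 0.412 (0.252 to 0.637), and Klf2, which controls T cell egress, 0.361 (0.273 to 0.468). Of 12 residency genes 3 were lower (percentile 27.92), of 10 recirculation genes 1, of 18 receptor and activation genes 2 (percentile 59.11) and of 17 immediate early genes 3 (percentile 22.62), among them Jund (0.425). Irf7 (0.152) and Rtp4 (0.214) were the lower 2 of 17 interferon genes, and Socs1 (0.0667), Cxcl10 (0.488) and Irf1 (0.499) the lower 3 of 12 interferon gamma genes. Nfkbia (0.605) and Tnfaip3 (0.554) were lower among 12 NF-kappaB targets, and Ccl3 and Ccl4 among 11 cytokine genes. Transcripts of hepatocytes ran the other way. Saa2, an acute phase gene, was 49.1-fold higher (20.8 to 107) and Apoc1 135-fold (53.6 to 350), and 3 of 7 acute phase and 3 of 4 constitutive hepatocyte genes were higher. These values rest on 33 UMIs per list in the IL-22-positive cells, and each of the 6 higher genes had all of its UMIs there in 1 cell. The neutrophil list had Wfdc21 higher on 8 UMIs, and 2 complement genes were measured with neither different.

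Between 0 h and 12 h, the IL-22-positive T-cell-like cells were lower in glycolysis genes at 12 h, and several immediate early genes were lower too. Rgs1 had a ratio of 0.136 (0.0602 to 0.270), Ucp2, a mitochondrial carrier, 0.104 (0.0465 to 0.205), and Cd69 0.396 (0.228 to 0.659). Cd3e was lower too, at 0.396 (0.243 to 0.624), with a UMI in 27 of 40 cells at 0 h and 17 of 38 at 12 h. Of 14 immediate early genes 6 were lower, among them Fos (0.374, 0.279 to 0.496) and Jund (0.309, 0.210 to 0.444), and Hspa1b was higher but had a ratio of 0.897 without its top cell, with the list at percentile 17.67. Of 7 glycolysis genes 4 were lower (percentile 0.09), with Aldoa at 0.203 (0.0834 to 0.430) and Eno1 at 0.196 (0.0749 to 0.436). Il22 went from 6 UMIs to 0 and Rora was lower (0.179, 0.0199 to 0.771), 1 of 4 measured type 17 genes. The other named genes with low ratios were Tagln2 (0.148), Slc25a3 (0.154), AY036118 (0.166) and Shisa5 (0.204). Of the 10 named genes with low ratios, 5 were also lower in the B-cell-like cells, where 3 had too few UMIs, and 3 in the monocyte-like cells, where 1 was higher. Those with high ratios were Dbi (6.11-fold, and 2.08-fold without its top cell), Gm42418 (2.49-fold), Uqcrq (2.28-fold), Lars2 (2.18-fold), 2410006H16Rik, Ly6c2 (1.67-fold), Morf4l1, Nme2 and Tra2b.

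Fewer list members could be measured here, on 129564 and 96339 UMIs. Of 8 residency genes 3 were lower and of 8 recirculation genes 2, with Klf2 at 0.488 (0.354 to 0.665). Of 8 type 1 genes Gzma alone was lower, and it had a ratio of 1.32 without its top cell, while the list's median log2 ratio was -1.12 at percentile 0.265. Of 6 proliferation genes 4 were lower, and Hmgb2 went from 0.437 to 1.34 without the cell with most of its UMIs, while Ube2c and Mki67 each had their UMIs of 0 h in 1 cell. Hist1h2ae (0.0224), H2afx (0.0696) and Hist1h2ap (0.126) had ratios of 0.672, 0.269 and 1.34, each without its own top cell, and Gstp1 went from 1.89-fold to 0.909-fold. Of 8 interferon genes Ifi27l2a alone was lower, and of 6 NF-kappaB targets none differed. The 2 libraries also differed by a shift of 0.28 in log2 ratio under median-ratio scaling.

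IL-22-negative T-cell-like cells had more interferon-response transcripts at 12 h than at 0 h. Of 17 measured interferon genes 12 were higher and 0 lower, with a median log2 ratio of 1.06, above all 10000 random lists. Rsad2, an antiviral enzyme, was 6.93-fold higher (4.37 to 11.6), Ifit3 3.25-fold (2.53 to 4.21), Isg15, a ubiquitin-like modifier, 2.71-fold (2.54 to 2.88) and Bst2, which tethers virions, 1.94-fold (1.81 to 2.07). The chemokine gene Cxcl10 was 2.87-fold higher (2.58 to 3.20), and with Gbp2 and Cd274 it made 3 of 12 interferon gamma genes. A cluster led by interferon genes held 26 of these T-cell-like cells (1.01%) at 0 h and 222 (5.55%) at 12 h. With that cluster and the cell-cycle cluster left out, 3 of the 17 interferon genes were higher and the median log2 ratio was 0.41, still above all random lists, while the interferon gamma median turned from 0.38 to -0.19.

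**Figure D2:**
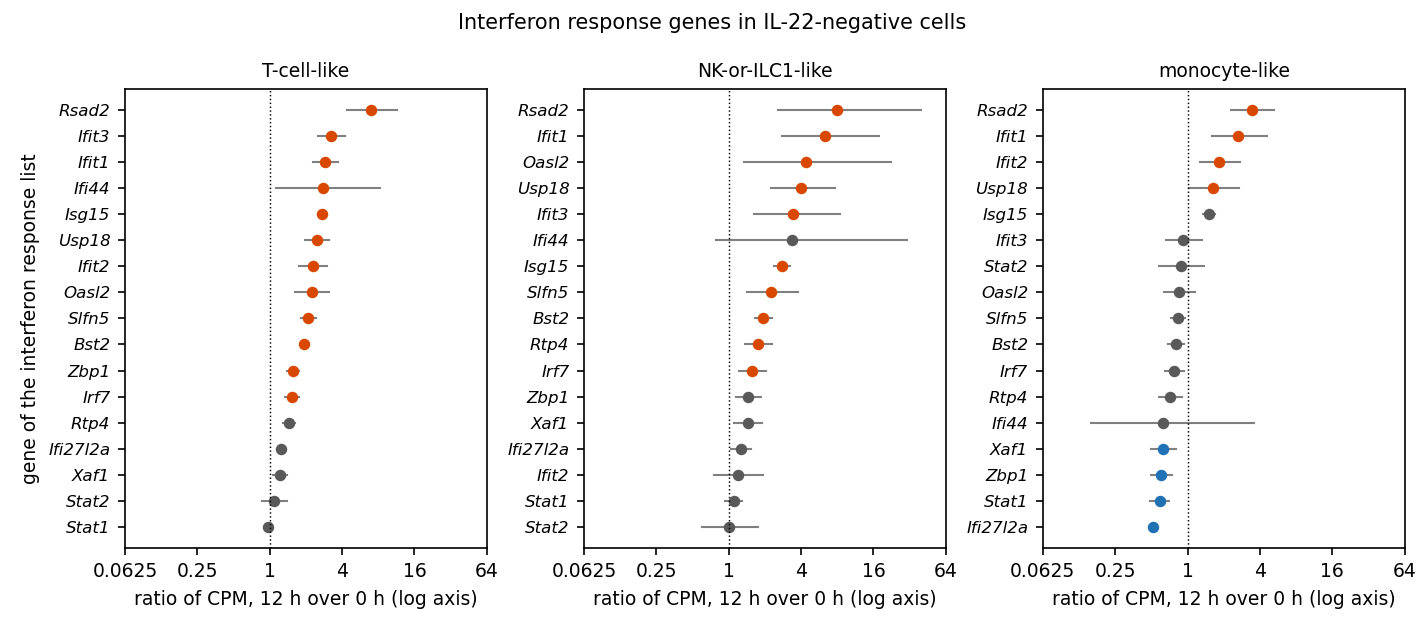
Ratio of CPM, 12 h over 0 h, on a log axis, for the 17 measured interferon-response genes in T-cell-like, NK-or-ILC1-like and monocyte-like cells of the IL-22-negative libraries, as points with exact 95% intervals as lines, orange where higher, blue where lower and grey where neither. In the T-cell-like cells 12 of 17 genes are higher and 0 lower, in the NK-or-ILC1-like cells 10 and 0, and in the monocyte-like cells 4 and 4.

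Genes of the type 17 list were also higher at 12 h in the IL-22-negative T-cell-like cells, with Il22 itself lower. Il17a went from 0 to 14 UMIs, at least 3.01-fold higher, while Il22 went from 13 UMIs to 1, a ratio of 0.0496 (0.00117 to 0.330). Ccr6 was 2.33-fold higher (1.68 to 3.29), Csf2, which encodes GM-CSF, 2.67-fold (1.14 to 7.22) and Ahr, a ligand-activated transcription factor of IL-22-producing cells, 1.72-fold (1.38 to 2.14). Thus 4 of 14 type 17 genes were higher and 1 lower, with a median of 0.52 above all random lists. Il17f was counted on 1 and 8 UMIs. Gzmb was 1.59-fold higher (1.49 to 1.70) and Xcl1, a chemokine for dendritic cells, 1.59-fold (1.5 to 1.69), the 2 higher of 12 type 1 genes. Divided by the same genes' ratios in monocyte-like cells these became 0.731 and 0.756. Of those monocyte-like cells 22.7% held a UMI of Cd3d, Cd3e, Cd3g, Il7r or Thy1. Dividing lymphocyte genes by them therefore cannot test the rise in T-cell-like cells. Ifng stood at 148 and 166 CPM. Other named genes with high ratios were Isg20 (2.53-fold), Phf11b (1.62-fold), Tmem176b (1.59-fold), Zbp1 (1.56-fold) and Fcer1g (1.51-fold).

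MHC class II genes and a few genes of other lists were lower in the IL-22-negative T-cell-like cells of 12 h. Tnfrsf4, which encodes the co-stimulatory receptor OX40, had a ratio of 0.432 (0.388 to 0.481), Pdcd1, the inhibitory receptor PD-1, 0.509 (0.365 to 0.708) and Egr1 0.584 (0.538 to 0.634). Tcf7, a transcription factor gene of naive and memory T cells, had a ratio of 0.7 and Fos 0.688, both named for their rank and short of a 1.5-fold difference. Cd74 (0.560, 0.533 to 0.588) and 2 other MHC class II genes of 9 were lower, with a median of -0.73 at percentile 0. The NK-or-ILC1-like cells showed nearly the same, with Cd74 at 0.551 and a list median of -0.79 at percentile 0, so the difference was not particular to T cells. B-cell-like cells went from 25.6% to 19.5% of the kept cells. The other named genes with low ratios, Top2b, Gm8369, Hnrnpdl, Hist1h1b and Crlf3, lay between 0.693 and 0.714. Of 18 receptor and activation genes 3 were lower and Il2 higher (1.66-fold, 1.06 to 2.66), of 17 immediate early genes 2 were lower and of 12 residency genes Itgae (0.586). None of 10 recirculation genes passed the rule, although their median was -0.26 at percentile 0.

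Among the remaining lists of these cells, 3 of 13 proliferation genes were higher, with Ccnb2 at 2.07-fold (1.58 to 2.72), and the cell-cycle cluster held 1.94% and 3.25% of the cells. Hk2, which starts glycolysis, was 3.03-fold higher (1.92 to 4.97), 1 of 14, and Bcl3 (1.70-fold) was 1 of 12 NF-kappaB targets. Of 12 cytokine genes 4 were higher, among them Cxcl2 (2.84-fold, 2.25 to 3.63) and Il1b (3.87-fold, 1.81 to 9.46). Il1b, a myeloid cytokine gene, went from 8 to 48 UMIs in T-cell-like cells and from 271 to 2846 UMIs in all IL-22-negative cells, a difference not particular to T cells. S100a8 (4 to 69 UMIs) and Cd14 (2 to 21) were likewise higher among 10 neutrophil genes and C1qb (2 to 22) among 2 complement genes. So were 5 of 6 acute phase hepatocyte genes, with Saa3 going from 0 to 31 UMIs, and Trf among 3 constitutive ones.

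NK-or-ILC1-like cells of the IL-22-negative libraries shared the interferon response. Of 17 interferon genes 10 were higher and 0 lower (median 0.96, above all random lists), with Rsad2 at 7.91-fold (2.55 to 39.7) and Isg15 at 2.78-fold (2.38 to 3.25). Cxcl10 was 3.14-fold higher (2.54 to 3.92), Gzmb 1.62-fold (1.53 to 1.72), Gzmc, another granzyme, 1.96-fold (1.72 to 2.24), Bst2 1.94-fold and Trim30a 1.82-fold. Named genes with low ratios were Hist1h2ae (0.445), Egr1 (0.446, 0.363 to 0.547), Cd74 (0.551), Hist1h1b (0.553) and Azi2 (0.577). Of 8 MHC class II genes 4 were lower, and of 10 recirculation genes Ccr7 and S1pr4 were lower.

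Monocyte-like cells of the IL-22-negative libraries had more neutrophil-type, complement and glycolysis transcripts at 12 h than at 0 h. S100a8, a calcium-binding alarmin, went from 6 to 8995 UMIs, 312-fold higher (143 to 852), and its partner S100a9 was at least 67.9-fold higher. Lrg1, a secreted glycoprotein, was at least 87.3-fold higher, Ifitm1 215-fold (38.5 to 8502) on 1 UMI at 0 h, and Lcn2, which binds bacterial siderophores, 77.5-fold (37.6 to 193). In the B-cell-like cells of the same libraries S100a8 stood at 1.53 and 9.37 CPM. Of 12 neutrophil genes 9 were higher (median 2.10), and neutrophil-like cells went from 0.261% to 0.824% of the library. Of 5 complement genes 4 were higher, with C1qb, a part of the first complement component, at 143-fold (25.6 to 5655) on 1 UMI at 0 h. Hbb-bs and Hbb-bt also met the naming rule, but 2 cells held 98.3% of the haemoglobin UMIs of the library of 12 h.

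Metabolic and inflammatory genes moved with them in these monocyte-like cells. Of 13 glycolysis genes 8 were higher (median 0.91, above all random lists), among them the glucose transporter gene Slc2a1 (4.5-fold, 1.87 to 14.1) and Hif1a, the hypoxia-inducible factor (2.19-fold, 1.68 to 2.90). Of 16 cytokine genes 7 were higher, with Il1b at 3.01-fold (2.49 to 3.68) and the neutrophil attractant Cxcl2 at 2.19-fold (2.04 to 2.36). Of 10 MHC class II genes 4 were higher, with H2-Eb1 at 2.06-fold (1.83 to 2.32). The interferon list leaned lower, with a median of -0.27 at percentile 0.28, while its genes went both ways, with Rsad2 at 3.41-fold (2.31 to 5.24) and Ifi27l2a at 0.515 (0.489 to 0.543) among 4 higher and 4 lower of 17. Cx3cr1, the fractalkine receptor of patrolling monocytes, was lower at 0.356 (0.283 to 0.448), with Rnase6 (0.278), Pglyrp1 (0.289) and Gstm1 (0.409). Ccl5 (3.26-fold) and Gzma (2.36-fold), genes of lymphocytes whose RNA part of these cells held, were among 4 higher type 1 genes of 11.

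The cDC-like and B-cell-like cells of the IL-22-negative libraries differed in other genes. In cDC-like cells Ifitm1 was 18.7-fold higher (13.9 to 25.9), AA467197 5.35-fold, Wfdc17 3.22-fold, the metallothionein gene Mt1 2.80-fold and Flot1 2.66-fold. Their interferon list had 9 of 17 genes higher and Bst2 lower (median 0.73), and their glycolysis list 5 of 14 higher. Capg (0.273), Ly6d (0.297), Sdc4, Upb1 and Pafah1b3 were lower in them. In B-cell-like cells S100a6 was 2.78-fold higher (2.57 to 3.02), the lysosomal reductase gene Ifi30 1.61-fold, Pdcd4 1.58-fold, Ndufb1-ps 1.54-fold and Napsa 1.52-fold, while 4 of 16 interferon genes were higher and 1 lower (median -0.09, percentile 53.84). Fos (0.572), Jchain (0.559), Hist1h1b (0.552) and Gzma (0.499) were lower, and so was Hbb-bs, which turned from 0.00579 to 3.24 without 1 cell.

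In pDC-like cells, which specialise in type I interferon, the interferon list had 1 of 17 genes higher and 1 lower (median 0.07). Ifitm3 was 3.05-fold higher (2.18 to 4.36), Hist1h2ap 2.21-fold, Hmgb2 1.76-fold and Klk1b27 1.74-fold, and the sterol synthesis genes Hmgcs1 (0.553, 0.418 to 0.728) and Fdps (0.595, 0.534 to 0.663) were lower with Spn, Tapbp and Birc6. Ccl3 went from 1.87-fold to 1.24-fold without its top cell, and Ube2c, 1 of 5 higher proliferation genes of 12, from 9.83-fold to 1.40-fold. In plasma-cell-like cells 6 of 13 proliferation genes were higher (median 0.57), with Hist1h2ap at 3.48-fold, Pclaf at 2.39-fold, Tuba1b at 2.16-fold, Slpi at 2.0-fold and Isg15 at 3.01-fold, or 1.70-fold without its top cell. The chaperone genes Hyou1 (0.533) and Herpud1 (0.575), of the unfolded protein response, were lower with Ly6c2 (0.396), Itga4 and Crip1.

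Monocyte-like cells of the IL-22-positive libraries, compared by the same rule after the data were seen, also had more alarmin and interferon transcripts at 12 h. S100a8 went from 2 to 9096 UMIs, 678-fold higher (188 to 5597), S100a9 was at least 28-fold and Lrg1 at least 53.4-fold higher, and Lcn2 66.9-fold (30.7 to 182). Of 17 interferon genes 7 were higher and 0 lower (median 0.50, percentile 99.91), with Rsad2 at 5.29-fold (3.8 to 7.59) and Isg15 at 4.19-fold (3.67 to 4.82). Of 18 cytokine genes 9 were higher, among them the neutrophil attractant Cxcl1 (5.87-fold, 2.47 to 18.3) and Ccl2, the monocyte attractant (2.12-fold, 1.83 to 2.45). Of 13 glycolysis genes 7 were higher, with Bnip3, a hypoxia target, at 5.41-fold (2.45 to 14.9). Other named genes with high ratios were Ifitm1 (36.3-fold), Wfdc21 (at least 31.4-fold), Igfbp6 (18.6-fold), Slpi (6.84-fold), Isg20 (5.12-fold) and Mmp8 (4.87-fold).

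MHC class II genes moved the other way in the IL-22-positive monocyte-like cells. Cd74 had a ratio of 0.429 (0.417 to 0.442), and 4 of 10 class II genes were lower with 0 higher. Ace and Spn, marks of patrolling monocytes, had ratios of 0.162 and 0.302, and Klf2 0.317 (0.291 to 0.347). The stress gene Hspa1a (0.224), Pglyrp1 (0.228), Eif3m (0.323) and Bub3 (0.341) were lower too, while Lyz1 turned from 0.0903 to 2.98 without 1 cell and Gdf15 went from 0.204 to 0.780. A finer clustering placed 67.8% of these cells at 0 h and 34.3% at 12 h in a sub-cluster led by Ace and Ear2, and 24.7% and 45.8% in a sub-cluster led by Chil3 and F13a1, genes of classical monocytes. In the IL-22-negative monocyte-like cells the Ace sub-cluster held 25.4% and 21.2%.

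Within each time, IL-22-positive monocyte-like cells differed from IL-22-negative ones. At 0 h H2-Ab1 was 4.15-fold higher (3.65 to 4.73) and H2-Eb1 3.79-fold (3.34 to 4.30), 6 of 9 class II genes were higher (median 1.14), and C1qb was 201-fold higher (35.6 to 7961) on 1 UMI in the IL-22-negative cells. The anti-apoptotic gene Bcl2a1b was 5.13-fold higher (3.71 to 7.25), and Cebpb lower at 0.132 (0.111 to 0.155). At 12 h the glycolytic gene Hk2 was 3.01-fold higher (2.63 to 3.45), Mif, a cytokine, 2.51-fold (2.30 to 2.74) and Il1rn, the IL-1 receptor antagonist, 2.24-fold (1.85 to 2.73). All 10 measured type 1 and cytotoxic genes were lower at 12 h, with Gzma at 0.00557 (0.00114 to 0.0164) and Ccl5 at 0.212 (0.191 to 0.234). Over both times, 22.7% of the IL-22-negative monocyte-like cells held a UMI of Cd3d, Cd3e, Cd3g, Il7r or Thy1, against 1.16% of the IL-22-positive ones, so the lower values of lymphocyte genes were not shown to be a difference between monocytes. The mix of monocyte sub-clusters differed between these libraries, and the ratios were not adjusted for that mix.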

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

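Of the tests below, the 3 on the monocyte-like make-up of the IL-22-positive libraries and the 3 on Il22 and Il17a in T-cell-like cells were chosen after the results were seen, as were all ratios of IL-22-positive monocyte-like cells. The differences between the IL-22-positive and IL-22-negative libraries in how they moved from 0 h to 12 h were not tested, since each group has 1 library.

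T-cell-like shares moved in opposite directions in the 2 sorted fractions. They went from 13.8% to 2.82% of the IL-22-positive and from 32.0% to 41.2% of the IL-22-negative cells. The IL-22-positive T-cell-like cells numbered 40 and 38, while the monocyte-like cells beside them went from 146 to 1062. With the low-UMI clusters left out, most of the IL-22-negative rise was gone, as given above. In T-cell-like cells 4 genes were lower at 12 h in the IL-22-positive and higher in the IL-22-negative cells. Fcer1g had ratios of 0.663 (0.435 to 0.996) and 1.51, Ube2c of 0.0640 (0.00155 to 0.398) and 2.0, and Tmem176b of 0.280 (0.149 to 0.493) and 1.59. Phf11b had 18 UMIs against 0 in the IL-22-positive cells. Its ratios were 0.224 with 3 UMIs set for 0, with an upper limit of 0.306, and 1.62. In monocyte-like cells the lymphocyte genes Ccl5, at 0.651 (0.531 to 0.804) and 3.26, and Gzma, at 0.0144 (0.00282 to 0.0462) and 2.36, parted in the same way. So did the class II genes H2-Aa, at 0.584 (0.556 to 0.614) and 1.79, and H2-Eb1, at 0.590 (0.553 to 0.628) and 2.06. In the IL-22-positive cells of 0 h all UMIs of Ube2c and of Gzma lay in 1 cell each, and Ccl5 had a ratio of 2.52 without its top cell.

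The IL-22-positive libraries were made mostly of monocyte-like cells without Il22 UMIs. Lymphocytes that carried the reporter and shared a droplet with a monocyte may be set aside, since 1.16% (0.635 to 1.94) of the IL-22-positive monocyte-like cells held a UMI of Cd3d, Cd3e, Cd3g, Il7r or Thy1, against 22.7% (19.7 to 25.9) of the IL-22-negative ones. An exchange of the 2 libraries of 12 h is likewise argued against, because monocyte-like cells formed 6.07% of the library labelled IL-22-negative, under the 50.5% (44.6 to 56.4) of the IL-22-positive library of 0 h. Blue fluorescence other than new Il22 transcription, such as a lasting reporter protein or the cells' own fluorescence, stays open, as 0 of 1306 monocyte-like and macrophage-like cells allow up to 0.230% with an Il22 UMI and B-cell-like cells stood at 0.0250%. That limit is on captured UMIs, so whether monocytes transcribe Il22 was not tested and stays open too.

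At 12 h the IL-22-positive over IL-22-negative ratios of T-cell-like cells went with those of monocyte-like cells, with a Spearman correlation of 0.641 across 253 genes, which are not independent replicates, against 0.0648 at 0 h, although T-cell-like and B-cell-like cells gave 0.417 at 0 h and 0.537 between the IL-22-negative libraries. Transcript length is argued against as the whole cause, since the correlation was 0.606 (0.493 to 0.692) with length taken out, and so is GC content, with 0.643 (0.544 to 0.721). Free RNA of monocyte-like cells in the T-cell-like cells is argued against as the whole cause by a correlation of 0.589 (0.394 to 0.735). That value is over the 82 genes at least as abundant in T-cell-like cells. Lymphocyte RNA in the monocyte-like cells, which would touch these same genes, was not tested. Over both times, 22.7% of the IL-22-negative monocyte-like cells held a UMI of Cd3d, Cd3e, Cd3g, Il7r or Thy1, against 1.16% of the IL-22-positive ones. Free RNA in that direction therefore stays open. A difference in how the 2 libraries were sorted or prepared and a biological difference shared by all reporter-positive cells cannot be told apart, because each fraction of 12 h is 1 library. A part of the low ratios in T-cell-like cells may therefore belong to the library, and dividing by the monocyte-like ratio left 1 of the 20 named genes.

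In IL-22-negative T-cell-like cells Il22 UMIs were fewer and Il17a UMIs more at 12 h. For Il22, a few cells with several UMIs each could account for the difference, since 4 of 2571 cells against 1 of 4003 give a ratio of 0.161 (0.00326 to 1.62) that includes 1. For Il17a this is argued against, since 0 and 11 cells with a UMI give a ratio of at least 2.35, with a lower limit of 1.61. Whether cells with Il22 were sorted into the other library at 12 h stays open. The exact interval for 0 UMIs in its T-cell-like cells reaches 38.3 CPM, against 46.3 CPM (17 to 101) at 0 h. With 3 UMIs set for 0, as in the other limits for a count of 0, it would be 31.1 CPM. A biological difference between the 2 times stays open and was not tested.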

How the results depend on the processing

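Leaving out clusters 13 and 16 or the low-UMI clusters, leaving out the cell with the most UMIs of a gene, dividing by the monocyte-like ratio and all settings for IL-22-positive monocyte-like cells were chosen after the data were seen. No paired analysis was possible because the libraries all carry replicate number 1 and each group has 1 library. Of 219 values of class shares under other settings, 196 stayed within the interval of the reported value, 23 moved and 0 reversed. Of 1304 ratios of named genes 1174 stayed, 114 moved and 16 reversed, and of 541 list medians 425 stayed, 113 moved and 3 reversed. Except where a setting is itself the reason (fewer cells or genes), the cause was not tested.

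The monocyte-like share of the IL-22-positive library of 12 h, 78.8%, was 82.7% with the stricter filter on cells, 63.6% at Leiden resolution 2, 81.1% with classes from markers cell by cell and 81.1% without the low-UMI clusters. The ratios of IL-22-negative shares, 12 h over 0 h, were 1.10 for T-cell-like, 0.630 for B-cell-like and 1.44 for NK-or-ILC1-like cells with the stricter filter. With classes from markers cell by cell they were 1.07, 0.698 and 1.26, and 2.65 for monocyte-like cells. Without the low-UMI clusters they were 1.04, 0.614, 1.38 and 2.77, and without clusters 13 and 16 the T-cell-like ratio was 1.21. Thinned to 1000 UMIs, 0% of the IL-22-negative cells of 12 h held an Il22 UMI, in place of 0.0103%, with fewer UMIs drawn, and 3 of 20 named genes of IL-22-positive T-cell-like cells over time were named again.

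How many named genes an alternative names too depends on the minimum of UMIs, by construction, since more or fewer genes compete. With no minimum beyond 10 UMIs these were 4 (positive against negative at 0 h), 10 (at 12 h), 6 (positive over time) and 0 (negative over time) of 20 in T-cell-like cells. Of 10 they were 1 in B-cell-like, 0 in NK-or-ILC1-like, 5 in monocyte-like, 1 in cDC-like, 0 in pDC-like and 0 in plasma-cell-like cells. For IL-22-positive monocyte-like cells they were 7 over time, 6 against IL-22-negative cells at 0 h and 5 at 12 h, of 20. With 200 or more UMIs they were 10, 11 and 1 of 20 in the first 3 comparisons of T-cell-like cells, 5 of 10 in cDC-like, 5 in monocyte-like and 6 in pDC-like cells, and 11 and 7 of 20 for IL-22-positive monocyte-like cells over time and at 0 h. With doublet calls kept, 4 of 10 were named again in pDC-like cells, and without the top cell 11 of 20 in T-cell-like cells of 12 h, positive against negative.

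Divided by the monocyte-like ratio, 4, 1, 12 and 5 of the 20 genes of the T-cell-like comparisons were named again, in the order above. Reversed were Cebpb (1.27, from 0.167) at 0 h, Nme2 (0.903, from 1.59) in positive cells over time, and Cxcl10 (0.853), Gzmb (0.731), Tmem176b (0.546) and Xcl1 (0.756) in negative cells over time. For the lymphocyte genes Gzmb and Xcl1 the reversal does not bear on T-cell-like cells, since part of the negative monocyte-like cells held lymphocyte RNA. Without the top cell, Hist1h2ae (0.156), Hist1h2ap (0.300) and Gzma (0.758) reversed in T-cell-like cells of 0 h, Gstp1 (0.909) and Hist1h2ap (1.34) in positive T-cell-like cells over time, Hbb-bs (3.24) in B-cell-like cells, and Lyz1 in positive monocyte-like cells over time (2.98) and against negative ones at 0 h (0.485). There the left-out cell is itself the reason. Without clusters 13 and 16, Hist1h2ae (0.781) reversed at 0 h and Hist1h2ap (1.25) in positive T-cell-like cells over time, as did the medians of the interferon gamma list in negative T-cell-like cells (-0.19), and of the proliferation list in B-cell-like cells (-0.21) and in T-cell-like cells of 0 h, positive against negative (-0.28). Depth limits the T-cell-like cells of the IL-22-positive libraries, with 129564 and 96339 UMIs against 7002400 and 10868805 in the IL-22-negative ones.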

Other observations

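The counts of haemoglobin and acinar genes, the setting without clusters 13 and 16 and the ratios of IL-22-positive monocyte-like cells were chosen after the data were seen. Transcripts of 2 sources other than leukocytes were held by a few barcodes. Haemoglobin genes, which mark erythroid cells, had 9477 UMIs at 0 h and 9462 at 12 h in the IL-22-negative libraries, of which 2 cells held 99.2% and 98.3%, and 1 and 9 UMIs in the IL-22-positive ones. The pancreatic acinar genes Ctrb1, Prss2, Cela2a and Try5, chosen after they were seen, had 481 and 96 UMIs in the IL-22-negative libraries and 3 and 0 in the IL-22-positive ones, and 2 cells held 78.2% of those of 0 h.

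Il1b, which encodes IL-1 beta, was higher in the whole of both fractions at 12 h. It stood at 15.2 CPM at 0 h and 102 CPM at 12 h over all IL-22-negative cells, and at 256 and 608 CPM over all IL-22-positive cells, where the sort sets the share of myeloid cells. In NK-or-ILC1-like cells without clusters 13 and 16, 9 of 17 interferon genes stayed higher, with a median log2 ratio of 0.88. Saa3, an acute phase gene also made by macrophages, was 108-fold higher (52.4 to 269) in IL-22-negative and 114-fold higher (60.2 to 250.0) in IL-22-positive monocyte-like cells at 12 h. Apoc1 was 3.07-fold higher (1.52 to 7.24) in the latter.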
